A study of Mus musculus with 6 samples.

How the data were processed

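RNA from the epididymal white adipose tissue of 3 wild-type mice and 3 mice with an adipocyte-directed deletion of Cnot3 was labelled with biotin from 500 ng of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The version, settings and scaling target of MAS5 are not given in the sources used here. The mean signal without the highest and lowest 2% of probe sets differed between arrays by at most 0.07%, which shows that the arrays had been scaled to a common level before deposit, and no value lay below 1. MAS5 uses mismatch probes to correct for background, so signals of dim probe sets are noisy on a log scale. No control probe sets were in the table used, so RNA quality ratios were not computed.

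Groups and mouse numbers were taken from the sample titles, which name separate mice. The titles give the same numbers 1 to 3 in both groups, and nothing in the labels says that a number marks a shared litter or day, so the main test had no block. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

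Of 45037 probe sets, 34945 carried 1 gene name in the platform annotation, 932 carried several and 9160 were unnamed here. Entrez numbers of 34741 of the 34945 were found in a RefSeq gene table of the assembly GRCm38.p6, which was used for names only, and 0 symbols needed an update. Each of 18194 genes was represented by its named probe set with the highest mean signal over the 6 arrays. Genes whose representative lay below the 40th percentile of mean signal (51.6) were not tested, which left 12769 genes and set aside 5425. Of 5922 genes with more than 1 tested probe set, 153 had probe sets called in both directions.

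The test was limma (version 3.58.1, R 4.3.3) on log2(signal + 22.5), the offset being the 25th percentile of all values, with lmFit and eBayes with a trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over all tested genes. The median standard error of a log2 difference was 0.15. With 3 mice per group, p-values rest on 4 residual degrees of freedom per gene plus those borrowed across genes. Arrays were also simulated from the real means and SDs of the 12769 genes, each gene drawn independently, with 66 or 67 genes changed at each size. The test recovered 95.5% of genes changed by 2 on the log2 scale. It recovered 70.2% of those changed by 1 and 19.4% of those changed by 0.5. There were 3 false calls among 126, and 0 calls where nothing was changed. The real comparison called 5115 genes, far more than were changed in the simulation, so these shares do not give its sensitivity or error.

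The 37 gene lists cover the CCR4-NOT complex, other mRNA decay factors, adipocyte functions, stress and immune pathways, and the other cell types a fat pad can hold. Of 873 list entries, 90 had no probe set naming only that gene, Cfd, Cnot1 and Plin1 among them, and were not analysed here. Lists with at least 5 tested members (35) were tested with camera at a preset correlation of 0.01 and adjusted over the lists. An estimated correlation and ranks were tried as well, as set beforehand, and fry, which tests each list by itself, was added after seeing the data. Adjusted over the list alone, 22 macrophage markers were higher and 1 lower, 18 endothelial markers were lower, and 27 cell cycle genes were higher, against 22, 18 and 25 over all genes. For the other lists this count differed by at most 3 genes in either direction.

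Genes were named by this rule: Cnot3 and the other subunits of its complex; the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap; up to 3 members with the largest change in each list, or the brightest where none passed; and Adipoq, Lep, Cfd, Pparg, Ucp1, Tnf, Ccl2, Saa3 and Slc2a4. Clock and Hox genes in the closing part, and members outside this rule that make up counts of 5 or fewer, were chosen after their values were seen.

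Alternatives covered the offset (1, or the median of 88.6), the filter (none, or the 60th percentile), quantile normalization, centring on the median of tested genes or on ribosomal protein genes, the choice of probe set, every probe set tested singly, eBayes without trend or robust, array weights, the mouse number as a block, other thresholds, and each array left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting. No outlier test was made, since groups of 3 are too small for it.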

Results

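Whole epididymal white adipose tissue was profiled from 6 mice on the C57BL/6 background at 8 weeks of age, with 1 Affymetrix expression array per mouse. In 3 mice (CNOT3KO) the gene for CNOT3, which belongs to CCR4-NOT, the protein complex that shortens the poly(A) tails of mRNAs, had been deleted by a Cre recombinase driven from the adiponectin promoter, which is active in adipocytes. The other 3 mice were wild type (WT). Each array gave a signal for 45037 probe sets, with a median between 82.1 and 92.9 across arrays, and the number of arrays limits the precision of every value below. The comparison asked which mRNAs of the fat pad differ when its adipocytes lack CNOT3.

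Cnot3 itself was lower in the knockout tissue. Its brighter probe set read 301 ± 7.02 (SD, n = 3) in WT and 201 ± 25.6 (SD, n = 3) in CNOT3KO, which is 66.6% of the WT signal, with a log2 difference of -0.54 (SE 0.14, limma adjusted p = 0.0131). The other Cnot3 probe set read 264 ± 47.7 and 227 ± 24.1, a difference of -0.19 on the log2 scale that did not pass the test. The position of these probe sets relative to the deleted part of the gene was not analysed here, and other cells of the tissue keep the gene, so the fall checks the labels without measuring the deletion in adipocytes. Among the 14 tested genes of the complex and its Btg and Tob partners, 2 rose, 3 fell and 9 did not pass. Btg2, an antiproliferative partner of the deadenylases, rose 1.86-fold, and Tob2, a related partner, fell to 0.655 of WT. Btg2 lost its call without WT mouse 2 (log2 0.72) or CNOT3KO mouse 1 (0.74), and Tob2 without WT mouse 1 (-0.49) or 2 (-0.57) or CNOT3KO mouse 1 (-0.62) or 3 (-0.46). Cnot9 read 1.39-fold of WT (adjusted p = 0.0395), a call that was lost without any 1 of the WT mice (log2 0.41 to 0.56) or without CNOT3KO mouse 1 (0.49) or 2 (0.33). Cnot7, a deadenylase subunit, was called lower by 1 probe set (log2 -0.49) and higher when probe sets that can cross-hybridise were avoided (log2 0.37, adjusted p = 0.0428), so its direction depends on the probe set. The log2 differences of Cnot2, Cnot4, Cnot6, Cnot6l, Cnot8, Cnot10 and Cnot11 lay between -0.14 and 0.35, and none of these subunits passed the test as set beforehand. Cnot2 did when cross-hybridising probe sets were avoided (0.53), with array weights (0.25) or without CNOT3KO mouse 3 (0.32), Cnot6l with the mean of all probe sets (0.29), and Cnot11 with array weights (0.38) or without CNOT3KO mouse 2 (0.47). Cnot8 read -0.11 by its brighter probe set and 0.12 with the mean of all, and 1 of its 2 tested probe sets was called higher singly. Some of the calls given here as lost without 1 mouse were also lost under other processing choices.

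The knockout fat pad differed from WT over a large part of the measured genes. Macrophage markers, cell cycle genes and lysosome genes were higher, and endothelial markers, insulin signalling genes and some adipocyte genes, leptin among them, were lower, while adiponectin stayed within the spread between mice. As list tests these shifts were called with a preset correlation between genes, and 0 of the 15 list calls held with an estimated one. A higher correlation does not account for every lost call, since lists with an estimate below the preset value lost theirs too. With an estimated correlation camera also has only the 4 residual degrees of freedom. A lost call therefore does not show that a list was unshifted. Of 12769 genes tested, 5115 (40.1%) passed an adjusted p of 0.05, with 2959 higher and 2156 lower in CNOT3KO. A change of at least 2-fold was seen in 829 of the higher and 425 of the lower genes. The 3 CNOT3KO arrays lay entirely on one side of the 3 WT arrays in 51.7% of tested genes, against 10% by chance. With each array centred on the median of the tested genes, the split turned to 2318 higher and 2800 lower genes, so which direction held more genes depended on the scaling, and 4474 of the 5115 genes kept their call.

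**Figure D1:**
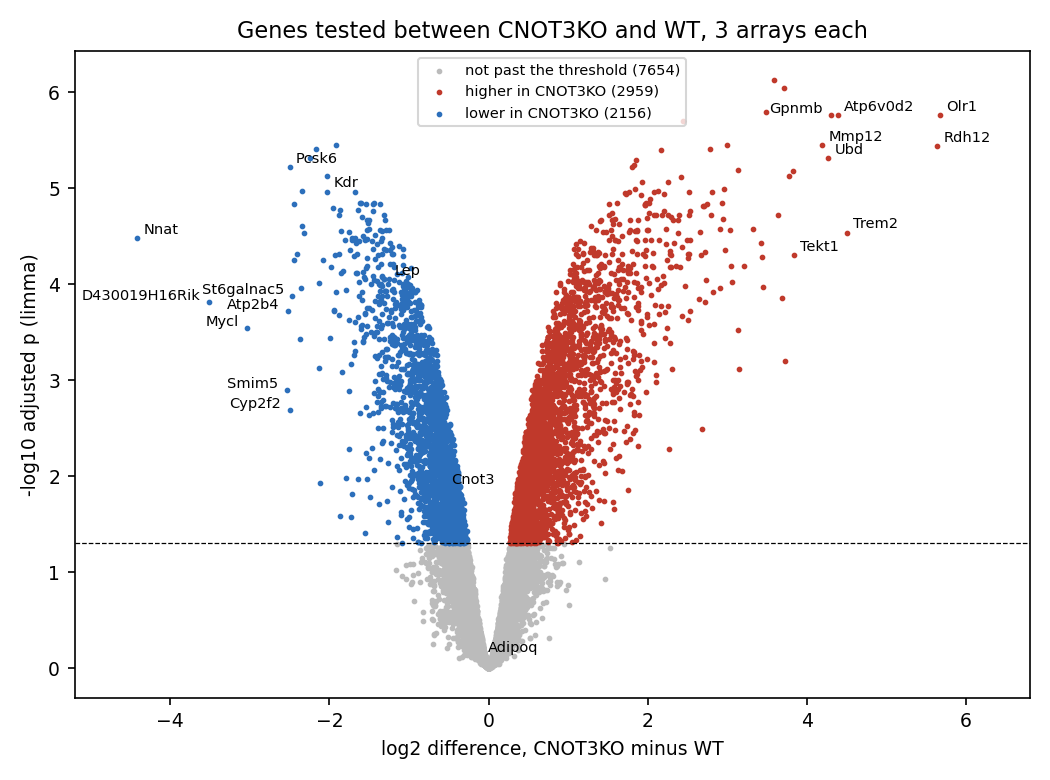
Each point is 1 of 12769 tested genes, with the log2 difference of CNOT3KO minus WT (3 arrays each) on the x axis and -log10 of the limma adjusted p on the y axis. Red points (2959) are higher and blue points (2156) lower in CNOT3KO past the dashed line at 0.05, and Olr1 at 5.68 and Nnat at -4.42 are the outermost labelled genes.

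The largest rise was in Olr1, a scavenger receptor for oxidised lipoprotein, from 18.6 ± 15.9 to 1997 ± 246 (SD, n = 3 each; log2 5.68, SE 0.24, limma adjusted p = 1.7e-06). Rdh12, a retinol dehydrogenase, rose from 21.6 ± 11.02 to 2214 ± 723, and with the offset at the median of all values it exceeded Olr1 (log2 4.34 against 4.29). Trem2, a lipid-sensing receptor of macrophages, rose 22.7-fold, Atp6v0d2, a subunit of the vacuolar proton pump, 20.9-fold, and Gpnmb, a glycoprotein of lysosome-rich phagocytes, 19.7-fold. Ubd, a ubiquitin-like protein, rose 19.3-fold, Mmp12, the macrophage elastase, 18.2-fold, and Tekt1, a protein of ciliary microtubules, 14.3-fold. The largest fall was in Nnat, an imprinted gene expressed in adipocytes, from 7411 ± 3273 to 311 ± 110 (log2 -4.42, SE 0.36, limma adjusted p = 3.3e-05). D430019H16Rik fell to 0.0878 and Mycl, a Myc family transcription factor, to 0.123 of WT. Smim5, Atp2b4, Cyp2f2, Pcsk6 and St6galnac5 fell to between 0.173 and 0.181 of WT. Fold values throughout are on the scale of log2(signal + offset), and those of genes that are dim in 1 group depend on the offset: between an offset of 1 and one at the median of all values, the log2 difference of Trem2 went from 5.18 to 3.52 and that of Tekt1 from 4.90 to 2.74. With the mean of all probe sets Trem2 rose by 1.88 log2 units.

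Most macrophage markers rose, by unequal amounts: 22 of 26 tested members were higher, 4 did not pass, and the median log2 difference was 1.79 (camera adjusted p = 5.8e-11; adjusted p = 0.467 with an estimated correlation). Trem2, Atp6v0d2, Gpnmb and Mmp12 were among the steepest, with log2 differences of 4.51, 4.39, 4.30 and 4.19, in an order that changed with the offset (3.52, 3.88, 3.99 and 3.80 with the median of all values). Of the cytokine, chemokine and acute phase genes, 14 of 27 rose and 1, Cxcl9, fell (median 0.62, camera adjusted p = 0.000766; adjusted p = 0.413 with an estimated correlation). Il1rn, the antagonist of the interleukin 1 receptor, rose 7.77-fold, the acute phase gene Saa3 6.54-fold, Lcn2 6.25-fold and the monocyte chemokine Ccl2 3.84-fold. Tnf read 41.9 ± 19.3 in WT and 51.8 ± 13.9 in CNOT3KO and was too dim to be tested. Lysosome genes moved with the macrophage markers, with 19 of 26 higher and 1, Atp6ap1, lower (median 0.66, camera adjusted p = 2.0e-06; adjusted p = 0.322 with an estimated correlation). Gla, a lysosomal galactosidase, rose 3.98-fold, Lipa, the acid lipase, 3.59-fold and Naglu 3.07-fold. Interferon-stimulated genes were higher in 19 of 25 cases (median 0.63, camera adjusted p = 2.0e-06; adjusted p = 0.488 with an estimated correlation), among them Zbp1 at 4.92-fold, Ifit1 at 4.24-fold and Usp18 at 3.63-fold. With the offset at the median of all values, Ifit1 exceeded Zbp1.

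Genes of the cell cycle rose as a group in the same tissue in which macrophage markers rose. Of 28 tested members 25 were higher, 3 did not pass, and the median log2 difference was 1.46 (camera adjusted p = 1.2e-11; adjusted p = 0.262 with an estimated correlation). Cdk1, the mitotic kinase, rose 7.02-fold, Mki67, a proliferation marker, 5.68-fold and Tk1, thymidine kinase, 3.98-fold. Of the p53 target genes, 9 of 20 rose and 1, Fas, fell (median 0.38, camera adjusted p = 0.0147; adjusted p = 0.322 with an estimated correlation). Cdkn1a, a cyclin-dependent kinase inhibitor, rose from 420 ± 51.7 to 5254 ± 272 (SD, n = 3 each), or 11.97-fold, while Eda2r and Tnfrsf10b, both members of the TNF receptor family, rose 2.33-fold and 2.70-fold. Tnfrsf10b read only 21.3 ± 16.3 in WT, so the size of its rise depends on the offset. Cell death pathway genes were higher in 10 of 18 cases and lower in 1, Bcl2 (median 0.51, camera adjusted p = 0.00255; adjusted p = 0.265 with an estimated correlation), with Casp1 at 2.93-fold and Casp4 at 2.85-fold, both inflammatory caspases, beside Zbp1. Of 32 matrix genes 18 rose and 2, Ccn2 and Thbs2, fell (median 0.54, camera adjusted p = 0.00281; adjusted p = 0.630 with an estimated correlation). Timp1, an inhibitor of metalloproteinases, rose 11.3-fold, Mmp2 2.61-fold and the collagen gene Col1a1 2.48-fold.

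Adipocyte genes did not move as one. Of 22 tested adipocyte identity and adipokine genes 8 fell, 1 (Slc36a2) rose and 13 did not pass (median -0.26, camera adjusted p = 0.000766; adjusted p = 0.504 with an estimated correlation). Lep, the gene for leptin, fell from 10667 ± 746 to 4489 ± 655 (SD, n = 3 each; log2 -1.25, SE 0.12, limma adjusted p = 8.9e-05). Aqp7, the glycerol channel, fell to 0.488 of WT, but had a log2 difference of -0.37, no longer called, when cross-hybridising probe sets were avoided, against -1.03. Adipoq, the gene for adiponectin, read 28794 ± 6538 and 26934 ± 4407, and Pparg, the regulator of adipocyte differentiation, 6897 ± 1320 and 5817 ± 396, with neither difference past the test, although Pparg passed without WT mouse 1 (log2 -0.39). Insulin signalling and glucose uptake genes were lower in 12 of 23 cases and higher in 2, Pdk4 and Slc2a1 (median -0.39, camera adjusted p = 0.00026; adjusted p = 0.322 with an estimated correlation). Pck1, the gluconeogenic and glyceroneogenic kinase, fell to 0.346 and Grb14, an adaptor that binds the insulin receptor, to 0.312 of WT, whereas Pdk4, an inhibitor of pyruvate dehydrogenase, rose 3.98-fold. Slc2a4, the insulin-responsive glucose transporter, read 4816 ± 851 and 3752 ± 913 and did not pass, although it did with array weights (log2 -0.54) and without WT mouse 3 (-0.52) or CNOT3KO mouse 3 (-0.56).

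Fatty acid oxidation genes rose in 13 of 21 cases (median 0.50, camera adjusted p = 0.000766; adjusted p = 0.599 with an estimated correlation), with the peroxisomal enzyme Ehhadh at 3.77-fold, Etfdh at 2.22-fold and Hadha at 2.04-fold. Sterol synthesis genes rose in 10 of 18 cases (median 0.55, camera adjusted p = 0.000766; adjusted p = 0.630 with an estimated correlation), with Dhcr7 at 4.92-fold and Cyp51 at 4.27-fold. Lss read 3.997-fold of WT (log2 1.999) but had a log2 difference of 0.46, no longer called, when cross-hybridising probe sets were avoided. Lipid droplet and lipolysis genes went both ways, with 4 of 17 higher and 6 lower and no shift of the list (camera adjusted p = 0.510): the droplet coat genes Plin2 and Plin3 rose 2.75-fold and 2.95-fold, beside Cidea and Hilpda. Of the brown and beige adipocyte markers 5 of 12 rose and 3 fell, also with no shift of the list (camera adjusted p = 0.576). Elovl3, a fatty acid elongase, rose 9.21-fold, Cox7a1 6.47-fold and Cidea, a droplet protein, 4.80-fold, while Ebf2, a transcription factor of brown and beige cells, fell to 0.468 of WT. Elovl3 read only 32.2 ± 14.0 in WT, so the size of its rise depends on the offset. The other calls of this list were rises of Cox8b and Kcnk3 and falls of Ppargc1a and Prdm16.

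Endothelial markers fell in 18 of 19 cases (median log2 -0.99, camera adjusted p = 5.8e-11; adjusted p = 0.248 with an estimated correlation). Kdr, a receptor for VEGF, fell from 1495 ± 41.3 to 353 ± 49.6 (SD, n = 3 each), Robo4 fell to 0.334 and Gpihbp1, which anchors lipoprotein lipase on capillaries, to 0.320 of WT. Smooth muscle and pericyte markers were lower in 9 of 13 cases and higher in 2, Cspg4 and Des (median -0.72, camera adjusted p = 0.00578; adjusted p = 0.413 with an estimated correlation), with Kcnj8 at 0.401 and Rgs5, a pericyte marker, at 0.408 of WT. Synpo2 read 0.354 of WT (log2 -1.50), but with all its probe sets averaged the log2 difference was -0.26 and not called. Mesothelial markers fell in 6 of 14 cases (median -0.54, camera adjusted p = 0.00151; adjusted p = 0.488 with an estimated correlation), with Msln at 0.485 of WT, Krt18 at 0.575 and Upk3b at 0.583, the last losing its call without WT mouse 2 (log2 -0.68). Hypoxia response genes held 3 risers (Pgk1, Slc2a1 and Tpi1) and 7 fallers of 20 with no shift of the list (camera adjusted p = 0.510). Vegfa, the endothelial growth factor, fell to 0.340, Ndrg1 to 0.362 and the oxygen sensor Egln1 to 0.411 of WT.

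**Figure D2:**
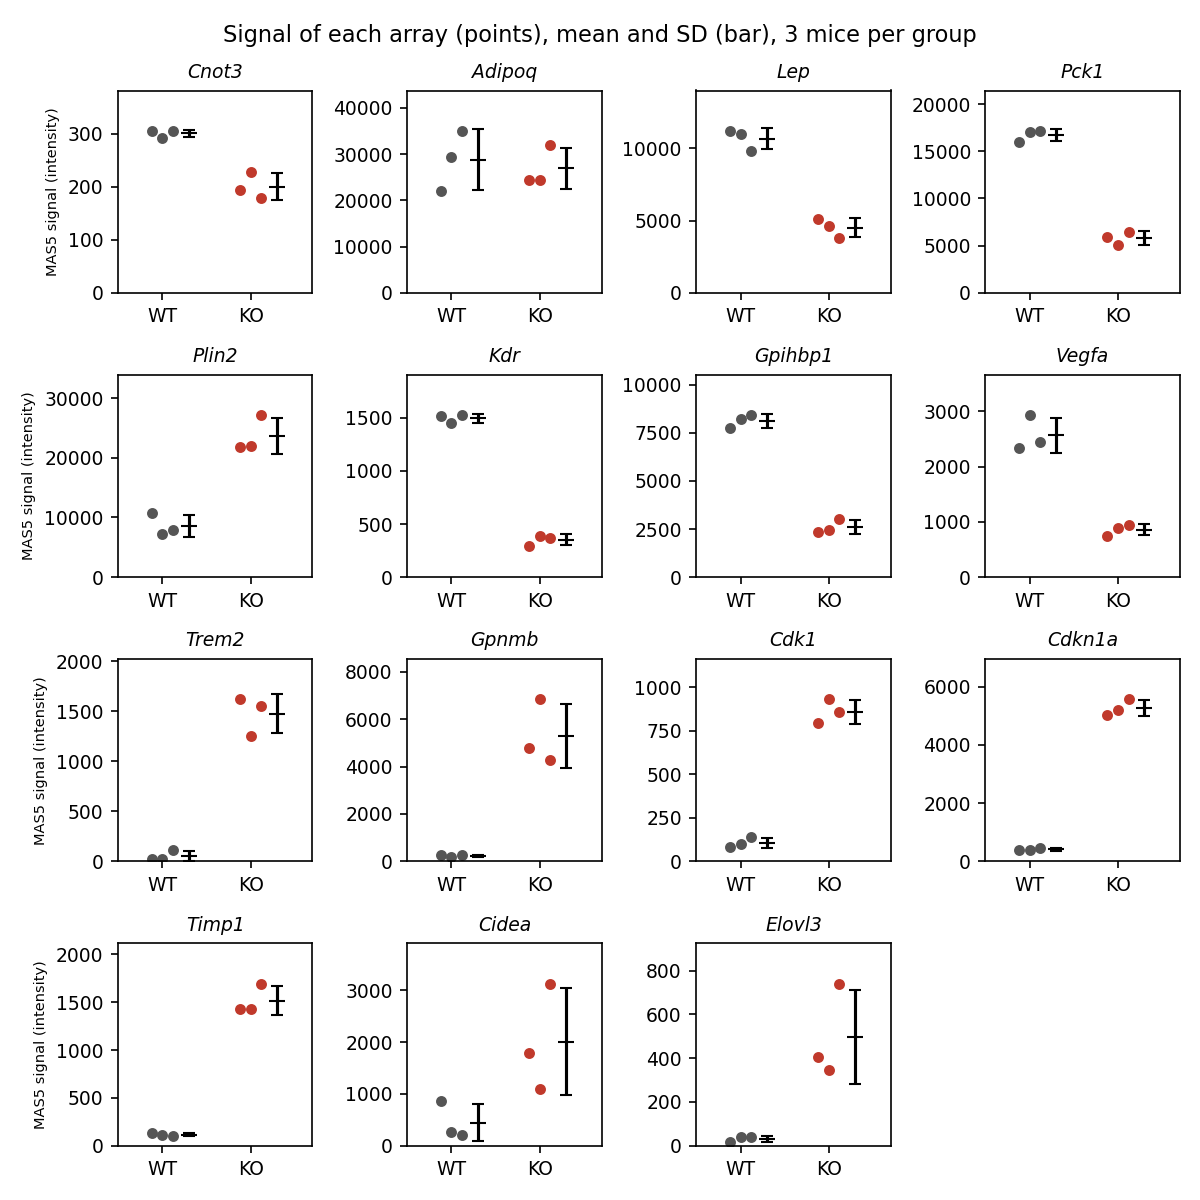
Points are the signals (intensity, linear axes from 0) of 3 WT and 3 CNOT3KO (KO) arrays for 15 genes, and bars give the mean and SD of each group. Adipoq overlaps between the groups, while Lep, Kdr and Vegfa lie lower and Cdk1, Cdkn1a and Gpnmb higher in all 3 CNOT3KO mice.

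The remaining lists were not shifted by camera at its preset correlation. Other mRNA decay factors held 6 higher and 6 lower genes of 30 (camera adjusted p = 0.979), with the exosome genes Exosc7 and Exosc4 up 2.21-fold and 2.02-fold and Tnrc6b, a partner of Argonaute, down to 0.576 of WT. The list of the CCR4-NOT complex itself was not shifted (camera adjusted p = 0.890). Fatty acid and triglyceride synthesis held 5 higher and 2 lower genes of 24 (camera adjusted p = 0.668), the higher ones being Acacb, Pgd, Slc25a1, Scd2 and Agpat2 and the lower ones Dgat2 and Lpin1, a phosphatidate phosphatase at 0.635 of WT. Acacb lost its call with the mean of all probe sets (log2 0.21), and Scd2 without WT mouse 2 (0.80) or 3 (0.56) or any 1 of the CNOT3KO mice (0.83 to 0.98). The groups of Scd2 overlapped, and its call was also lost under several processing choices. Among these were quantile normalization (0.89), centring on the median (0.81) or on ribosomal protein genes (0.92), and the mean of all probe sets (0.67). Of the TCA cycle and branched-chain amino acid genes 4 of 31 rose and 9 fell (camera adjusted p = 0.549), with Dlat at 2.30-fold beside Dld, Fh1 and Sucla2, and Acadsb at 0.599 of WT. Of 48 oxidative phosphorylation genes 5 rose (Uqcrc1 by 1.54-fold, Uqcrc2, Ndufs1, Ndufs4 and Ndufa9) and 4 fell (Cox4i1, Cox7c, Cox8a and Ndufa1; camera adjusted p = 0.974). Cox7c lost its call without WT mouse 3 (log2 -0.45) or CNOT3KO mouse 3 (-0.53), and Cox8a without WT mouse 2 (-0.44) or 3 (-0.39) or CNOT3KO mouse 1 (-0.41) or 2 (-0.37). Unfolded protein and integrated stress response genes held 8 higher and 5 lower of 22 (camera adjusted p = 0.510): Atf3, a stress-induced transcription factor, rose 4.86-fold, Sdf2l1 2.49-fold, and Phgdh, of serine synthesis, fell to 0.194 of WT, beside Asns, Ddit3, Atf4 and Ero1a. Among immediate-early and other short-lived mRNAs 8 of 27 rose and 6 fell (camera adjusted p = 0.668), with Egr2 at 5.56-fold and Fos at 4.78-fold. Egr1 read 2.67-fold of WT with overlapping groups. It lost its call without WT mouse 1 (log2 1.09) or 2 (1.16) or CNOT3KO mouse 1 (1.13) or 3 (1.42). Cytosolic ribosomal protein genes held 1 call among 35 tested, of Rps6 (log2 -0.36; camera adjusted p = 0.668), which was lost without any 1 of the WT mice (-0.39 to -0.31) or without CNOT3KO mouse 1 (-0.38) or 3 (-0.25) and read -0.05 with the mean of all probe sets. Reference genes held 3 higher and 1 lower of 11 (camera adjusted p = 0.668). Gusb, a lysosomal enzyme, rose 2.55-fold beside Pgk1 and Polr2a, the latter losing its call with the mean of all probe sets (log2 0.30), and Tfrc was lower by 1 probe set (log2 -0.65) but read 0.03 with the mean of all its probe sets, and its call was also lost with no filter on dim genes, without trend, without WT mouse 2 (-0.40) or 3 (-0.67) and without any 1 of the CNOT3KO mice (-0.69 to -0.59).

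Markers of further cell types were not shifted as lists either. Of 10 T and NK cell markers 2 rose (camera adjusted p = 0.549), Il7r, the interleukin 7 receptor, by 6.68-fold and Klrd1 by 1.72-fold. Of 10 B and plasma cell markers 3 fell (camera adjusted p = 0.0884), with Ms4a1 at 0.355 and Ebf1, which adipocytes also express, at 0.629 of WT, beside Cd79b. The list was shifted with no filter on dim genes (median -0.38), with arrays centred on ribosomal protein genes (-0.41) and without WT mouse 1 (-0.64). Ms4a1 lost its call with the mean of all probe sets (log2 -1.03) or without WT mouse 2 (-1.42), and Cd79b without WT mouse 2 (-0.96) or 3 (-0.98) or CNOT3KO mouse 3 (-0.63). Mast cell and eosinophil markers held 3 higher and 2 lower of 6 (camera adjusted p = 0.668), with the mast cell proteases Cpa3 and Cma1 at 3.15-fold and 2.61-fold and Gata2 and Kit lower. Mcpt4, another such protease, read 17.6 ± 15.9 in WT and was higher by an amount set largely by the offset (log2 2.80 with an offset of 1, 0.93 with the median of all values), and lost its call without CNOT3KO mouse 1 (1.41). The 5 neutrophil markers held 1 rise, of Lcn2, and 1 fall, of Mmp9 (camera adjusted p = 0.979), the latter lost without WT mouse 1 (log2 -0.96) or CNOT3KO mouse 3 (-0.95). Dendritic cell and MHC class II genes held 1 call among 12, of Itgae (log2 -0.44; camera adjusted p = 0.473), which was lost without WT mouse 1 (-0.44) or 2 (-0.34) or any 1 of the CNOT3KO mice (-0.46 to -0.42). Progenitor and fibroblast markers held 3 higher and 3 lower of 18 (camera adjusted p = 0.668), with Lum, a matrix proteoglycan, at 2.92-fold, Fap and Pdgfra also higher, and Ebf2, Pi16 and Zfp423 lower. Pdgfra lost its call without WT mouse 1 (log2 0.64) or CNOT3KO mouse 1 (0.815). Skeletal muscle markers held 1 call among 8, of Mb (log2 0.99; camera adjusted p = 0.974), which was lost without WT mouse 2 (0.82) or 3 (0.79) or CNOT3KO mouse 1 (0.92) or 2 (0.93). Schwann cell and nerve markers held 2 higher and 1 lower of 7 (camera adjusted p = 0.510). Sox10 rose 2.96-fold, while Cnp lost its call without WT mouse 2 (log2 0.39) or CNOT3KO mouse 1 (0.44) or 2 (0.40), and Stmn2 without WT mouse 1 (-0.49) or 3 (-0.53) or CNOT3KO mouse 2 (-0.52) or 3 (-0.45). Only 3 epididymis epithelium markers and 3 erythroid markers were bright enough to be tested, too few for a list test. Rnase10 of the former rose 1.65-fold, and Alas2 of the latter read 255 ± 70.4 and 157 ± 62.2 and did not pass, although it did without CNOT3KO mouse 3 (log2 -0.90).

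**Figure D3:**
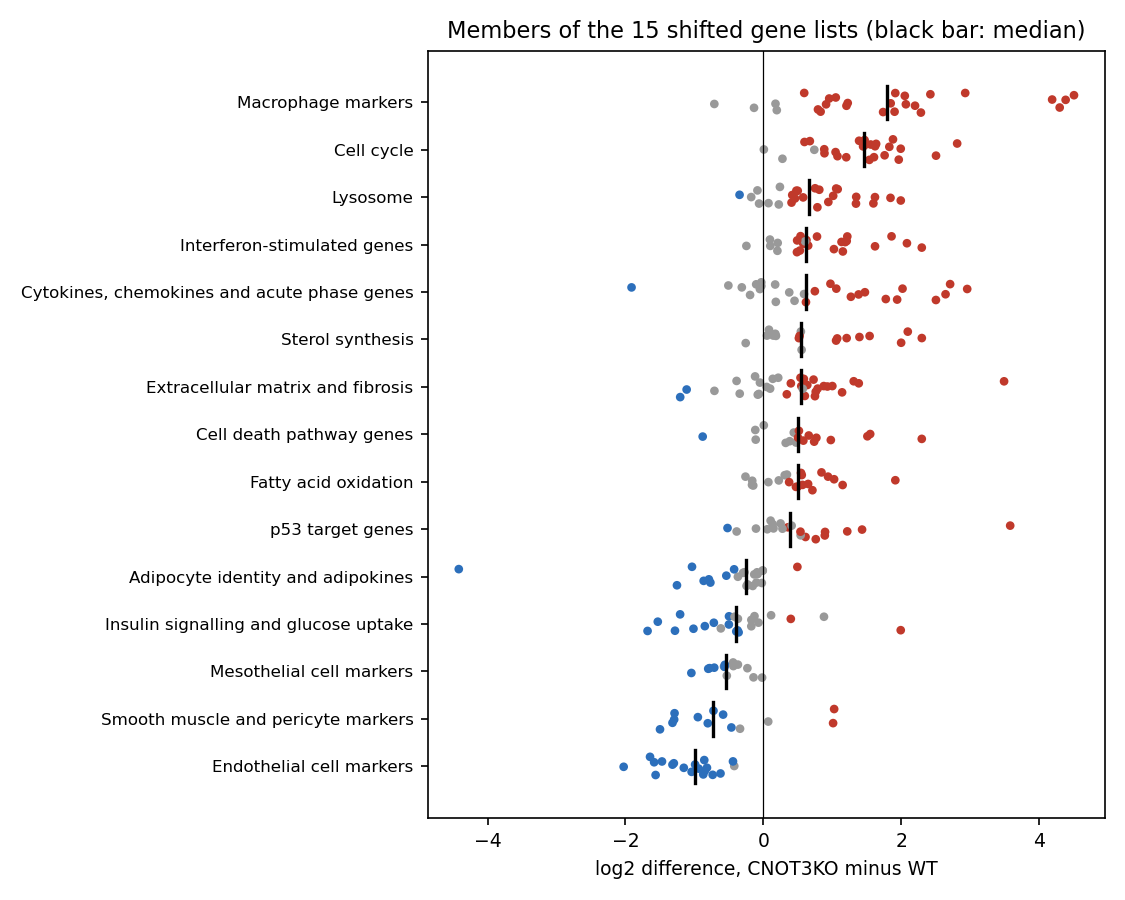
Each point is a tested member of 1 of the 15 shifted gene lists, placed by its log2 difference of CNOT3KO minus WT (x axis), red or blue where it passed an adjusted p of 0.05 and grey where it did not. Black bars are list medians, which run from 1.79 for macrophage markers to -0.99 for endothelial markers.

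In all, 15 of 35 lists were shifted with camera's preset correlation, 10 up and 5 down, and 0 with a correlation estimated from these 6 arrays, where 5 lists had an unadjusted p under 0.05. The p53 target and cell death lists lost their calls with estimates of 0.0049 and -0.0329, below the preset 0.01. For these lists a higher correlation is not what removed the call. With an estimated correlation camera uses the 4 residual degrees of freedom. With a preset one it uses degrees of freedom set by the number of tested genes. The settings thus differ in more than the correlation. Regrouping the same 6 arrays into other sets of 3 and 3 gave up to 19 shifted lists, while no single gene passed the adjusted threshold in those groupings. Each such set still holds 2 mice of one genotype and 1 of the other, so these counts are not those of unchanged lists. The genotype difference also adds to the spread within each such set, so the lack of called genes there does not argue against chance.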

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

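Both results here come from probe sets that the gene-level comparison did not use. Ucp1, the uncoupling protein of brown fat, read 76.2 ± 33.9 (SD, n = 3) in CNOT3KO against 6.50 ± 2.12 in WT, but its mean over the 6 arrays lay below the filter on dim genes, so it was not tested. Among the 3549 bright enough probe sets without a gene name, 208 were higher in CNOT3KO and 1142 lower, which is taken up under the other observations.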

How the results depend on the processing

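All alternatives here were planned, except fry, which was chosen after seeing the data. Cnot3 kept its direction and passed the threshold in all 19 alternatives that scored it, with log2 differences from -0.64 to -0.36 and limma adjusted p from 0.0027 to 0.0496. These leave out the test of every probe set singly and the 2-fold requirement. Singly, its brighter probe set passed (limma adjusted p = 0.0151) and the other did not (0.41). Its log2 difference of -0.54 does not reach a 2-fold change. Counts of changed genes stayed within 1.5 times of 5115 except with every probe set tested singly (9724, of which 4552 higher and 5172 lower) and with a further requirement of a 2-fold change (1254, of which 829 higher and 425 lower), both by construction. Leaving out 1 array gave 3820 to 4636 genes, with fewer arrays to estimate the spread. Centring on the median of tested genes gave 2318 higher and 2800 lower genes (45.3% higher against 57.9%). The estimated correlation left 0 of 15 lists, with 5 at an unadjusted p under 0.05, ranks 15 and fry 21. Fry called all 15 lists that camera had shifted. It also called the hypoxia list lower. The unfolded protein, Schwann cell and nerve, brown and beige, reference gene, and T and NK cell lists were called higher by fry. Fry does not compare a list with the other genes, and 40.1% of tested genes passed singly. Its calls therefore do not show a shift beyond that of the other genes. Among values of other lists and of named genes, 681 and 2161 stayed as they were, called or not, while 15 and 110 lost a call and 3 and 13 gained one. With the mouse number as a replicate block, 5092 genes changed (2910 higher, 2182 lower), and 4837 of the 5115 kept their call; Alas2 (log2 -0.66) and Cnot11 (0.35) gained one, and Cd79b, Itgae and Scd2 lost theirs. Same-numbered arrays had correlations of 0.07, 0.11 and 0.04 of their deviations from the group means, each array's highest with the other group. Only mouse number 2 exceeded the limit of 0.1 set beforehand, so whether the numbers pair the mice stays open.

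Of 5039 called genes tested with the mean of all probe sets, 147 turned sign, as did 39 of 5075 with cross-hybridising probe sets avoided. Of 46 results that changed direction among lists and named genes, 2 had passed the threshold: Cnot7 (log2 0.3671 when cross-hybridising probe sets were avoided) and Tfrc (0.0262 with the mean of all probe sets). The cause was not tested for these or for the following values near 0, which are log2 differences of genes, or medians of lists whose test changed direction. Without the filter, oxidative phosphorylation had 0.0374, neutrophil markers -0.1002 and skeletal muscle markers 0.0797. Quantile normalization gave 0.0978 for other mRNA decay factors, 0.0687 for oxidative phosphorylation, 0.0443 for ribosomal proteins, 0.0384 for Adipoq and -0.0054 for Cnot10. Centring on the median gave 0.0301 for other decay factors, -0.0775 for Cnot10 and -0.0137 for Cnot4. The mean of all probe sets gave 0.0706 for neutrophil markers (also on ranks), -0.1329 for skeletal muscle, -0.1626 for Cnot10, -0.0479 for Cnot11, 0.04 for Cnot6 and 0.1222 for Cnot8. Avoiding cross-hybridising probe sets gave 0.096 for the CCR4-NOT list and 0.0794 for oxidative phosphorylation. Array weights gave 0.0737 for other decay factors, -0.0139 for fatty acid synthesis, 0.0068 for short-lived mRNAs and -0.0108 for Cnot10.

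With 1 array left out, values ran from -0.0021 to 0.0836 for the CCR4-NOT list, 0.0763 to 0.1328 for other decay factors, 0.0053 to 0.2561 for fatty acid synthesis, -0.0215 to 0.0633 for oxidative phosphorylation, -0.1435 to 0.1526 for neutrophil markers, 0.0677 to 0.2729 for skeletal muscle, -0.2059 to -0.1001 for short-lived mRNAs and -0.0588 to 0.0519 for ribosomal proteins. The same ranges were -0.2651 to 0.0707 for Adipoq, -0.0522 to 0.0695 for Cnot10 and -0.0073 to 0.209 for Cnot4. Signals near background limit what can be said of dim genes such as Tnf and Ucp1.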

Other observations

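Genes of the circadian clock moved in opposite directions in the knockout tissue. Of 18 clock genes looked up after seeing the data, 15 were bright enough to be tested, 1 rose and 8 fell. Arntl, an activator of the clock, rose from 84.4 ± 18.8 to 354 ± 52.3 (SD, n = 3 each; log2 1.82, SE 0.18, limma adjusted p = 9.5e-05). The repressors Per1, Per2 and Per3 fell to 0.516, 0.425 and 0.297 of WT, and the clock output factors Dbp, Tef and Hlf to 0.316, 0.394 and 0.378. Nr1d2 and Ciart fell to 0.623 and 0.383, while Clock, Cry1, Cry2, Nr1d1, Bhlhe40 and Nfil3 did not pass. All 9 calls were kept under each of the 3 other scalings.

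Hox genes, which mark position along the body axis, were also picked out after seeing the data, and no list test was made of them. Of 18 tested, 9 fell and 9 did not pass, and 17 had a log2 difference below 0, while over all 12769 tested genes 2156 fell. Hoxc5 fell from 1845 ± 292 to 456 ± 119 (SD, n = 3 each), Hoxa7 from 428 ± 48.3 to 98.3 ± 34.4 and Hoxa5 from 762 ± 21.6 to 300 ± 48.9. Other scalings gave 7 to 12 lower Hox genes.

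The tests of the clock, of the cell type markers and of dim against bright probe sets were chosen only after the results were seen, as was centring the unnamed probe sets on ribosomal protein genes, while the tests of other groupings, of signal and of scaling were set before their outcome. Splitting the 6 arrays into 3 and 3 in all 10 ways, 1 split, the real one, gave as many changed genes as the real 5115, and the highest of the others gave 0 with limma at the adjusted threshold (316 at an unadjusted p under 0.05, against 6206). The same held for the 2959 higher and the 2156 lower genes (1 split each, and 0 in the highest of the others). The real split gave 15 shifted lists, 4 of the 10 splits gave as many or more, and the highest other gave 19. With 10 splits, no share under 0.05 can be reached. Every other split has 2 mice of one genotype and 1 of the other in each group. The genotype difference then adds to the spread within groups, which lowers the counts of called genes. The 0 against 5115 therefore does not argue against chance. Part of the genotype difference also remains between the groups, so the list counts are not those of unchanged lists.

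For the clock genes, collection of the groups at different times of day could also move Arntl against the Per genes, and the labels give no collection time. The log2 difference of Arntl exceeded the median log2 difference of Per1, Per2, Per3 and Dbp by 3.27, which restates the pattern and decides nothing. That explanation and an altered clock in tissue lacking CNOT3 cannot be told apart here.

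For the unnamed probe sets, 84.6% of those called were lower in CNOT3KO, against 48.2% of named ones. Named probe sets drawn at the same signals reached at most 53.3% in 1000 draws, which argues against low signal as the cause. The 3 other scalings left at least 80.6% lower, which argues against scaling. RNA from outside annotated gene ends, or RNA quality, could still contribute: the log2 difference of CNOT3KO minus WT was lower in the dimmest than in the brightest probe set of a gene, by a median of -0.033 (95% bootstrap interval -0.047 to -0.022, 5922 genes), which is small beside the median difference of -0.35 in unnamed probe sets. The positions of the unnamed probe sets were not analysed here, so this stays open beside a biological difference between the genotypes.

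For the mixture of cells, equal dilution of all other cells would lower their markers alike. The endothelial markers lay -0.83 log2 units from the progenitor and fibroblast markers in the median (19 against 18 genes, two-sided permutation p = 0.00012 over genes, which are not independent replicates, 0.00016 adjusted over 2 comparisons). The endothelial list was compared after its median (-0.99) was seen to be the lowest of all lists, so this p-value gives no independent support. Smooth muscle and pericyte markers (median -0.72) and mesothelial markers (-0.54) fell as well. The medians fell unequally, and whether dilution was part of this is not decided here. None of the macrophage or endothelial markers tested is in another list. The 26 macrophage markers changed unevenly, with log2 differences from -0.71 to 4.51 and an SD of 1.41 against a median SE of 0.19. For these markers, that argues against an equal rise in all macrophages of unchanged expression as the only cause, unless other cells also express some of them. A rise in only some kinds of macrophage was not tested and could also give uneven changes. How much came from cell number and how much from expression per cell stays open, since whole tissue cannot separate these.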
